A study of Sus scrofa with 24 samples.

How the data were processed

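Small RNA in serum was measured on single-colour Agilent microRNA arrays, and every value here was computed from the deposited scanner files of 24 arrays. Per the labels, the authors extracted the images with Agilent Feature Extraction 10.7, and the file headers give version 10.7.3.1. The processed signal in the deposited scanner files is an intensity on a linear scale, per the file headers. The deposited value table holds values read as log2 ratios that the authors centred within each day. That scale and the centring were inferred from the values (each day's probe medians lay within 4.8e-07 of 0), and the normalization method behind them is unknown.

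Each array held 12600 spots for miRNA probes, belonging to 1635 probes and 630 miRNA entries. Of these entries 373 were human, 235 porcine, 13 murine and 9 bovine sequences. A probe had 5 to 20 spots (median 10). Control spots and spots with an outlier flag of the scanner software were left out, which removed 3.32% of the spots. The remaining spots of a probe were averaged on the linear scale. A probe counted as above background on an array when a share of at least 0.5 of its used spots carried the scanner's flag for signal well above background. The signal of each array was divided by the array's 75th percentile over the 28 probes above background on all 24 arrays. Scaled signals below a floor of 0.0324 were set to the floor (log2 -4.95), the median over arrays of the 5th percentile of the scaled signals of probes above background. The log2 was then taken. Of several probes for an entry, the one with the highest mean represented it. An entry was tested when this probe was above background on at least 4 of the 24 arrays, whichever groups they belonged to. This left 56 entries (33 human, 19 porcine and 4 bovine), and 35.3% of their values lay at the floor.

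A model of 6 group means (reproductive status and day) was fitted to all entries with limma 3.58.1 (lmFit, contrasts.fit and eBayes, 18 residual degrees of freedom) in R 4.3.3. The model had 13 contrasts: pregnant against cyclic on each of the 3 days and over their mean, the differences between days in that status effect, and the days within each status. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was the threshold. Intervals are 95% confidence intervals from the same model. Numbers of detected entries were compared within each day by a two-sided exact permutation test over all 70 assignments of 8 arrays, whose smallest possible p is 0.0286.

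The miRNAs named in the text followed a rule. For each contrast of pregnant with cyclic animals these were the entries that passed, and, where fewer than 10 passed, those with the next smallest p up to 10, given as not passing. For every other contrast they were up to 5 passing entries in each direction, or the 3 with the smallest p if none passed. The 10 brightest names over all arrays were added, as were members of the lists below that passed or otherwise up to 4 of their brightest members. A porcine entry was preferred over others of the same name. An entry that was not above background on any array of a group has no measured level there, so differences that rest on that group take no value in the report. For a comparison of 2 groups a lower bound of the fold is given instead, from the mean of the measured group down to the lowest signal above background on each array of the other group, averaged over those arrays. No fold is given where the measured mean did not exceed that level. Arrays of the measured group that did not detect the entry enter its mean at their signal or the floor. Where such arrays exist, the true fold may be smaller than the bound.

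A set of 19 miRNA lists was compiled from general knowledge. It held markers of red cells, platelets, white cells, liver and muscle, the miR-200, let-7 and miR-30 families, and the miR-17 (with its paralogs), miR-99 and miR-125, DLK1-DIO3, X-linked miR-424 and miR-503, miR-371 and miR-302, C19MC and miR-183 clusters. The other lists covered angiogenesis, ovary, smooth muscle and stroma, and inflammation. Lists with at least 3 tested members were tested with limma's fry (whether members move, on balance, in the same direction) and camera (whether they differ from the other entries, with a preset correlation of 0.01 and, as an alternative, an estimated correlation). P-values were adjusted over the lists within each contrast. The groups, contrasts, thresholds, lists, naming rule and most alternative settings were chosen before the data were examined.

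Alternatives changed a single choice at a time, except that normexp background correction replaced the processed signal by the median spot signal and added an offset of 50. The others were quantile normalization, that offset added to the processed signal, the 75th percentile over all probes, the median in its place, no normalization, the mean over the probes of an entry, a floor 4 times lower, the scanner software's total gene signal and the value table. Further ones were detection on at least 12 arrays or no filter, porcine entries alone, a block for slide or for the replicate number, the groups of a day compared alone, eBayes with trend and robust estimation, other detection rules, and each array left out in turn.

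The arrays lay on 3 slides of 8, and each slide held arrays of all 6 groups. Same-numbered cyclic and pregnant arrays of a day shared a slide and a column of it. All cyclic arrays lay in row 1 and all pregnant arrays in row 2, so row and status cannot be told apart. In simulated data with the group sizes, mean signals and residual SDs of these arrays, 10 of 56 entries were changed in each of 20 datasets. The changed entries were drawn from the 35 detected on at least 12 arrays, and the noise was independent between entries. The recovery therefore does not cover the dimmer entries or entries that vary together. The model called 80 of 200 changed entries (40%) at a 2-fold change, 136 (68%) at 4-fold and 162 (81%) at 8-fold. False calls numbered 7, 8 and 10 in all.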

Results

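Circulating microRNAs were profiled in serum of Hampshire x Duroc gilts that were either pregnant or in the estrous cycle, on days 12, 16 and 20. Blood was drawn post mortem. Each of the 6 groups held 4 animals, each measured on its own array, 24 arrays in all. Values are log2 of the signal of an entry relative to its array's 75th percentile, and group values are means ± SD with n = 4 unless stated otherwise. The entry names carry the species of the probe sequence (ssc for pig, hsa for human, bta for cattle). No genome was used here, so entries have no coordinates.

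Most of the array stayed dark. Between 17 and 63 of the 630 entries were above background on an array (median 37), 16 entries were so on all 24 arrays, and 547 were so on no array. The 75th percentile of the signal ran from 236 to 1381 (median 710), a 5.85-fold range. On day 12, 31.5 ± 4.44 entries were above background in pregnant and 43.8 ± 14.4 in cyclic animals (difference -12.3, exact permutation p = 0.171). Without cyclic day 12 replicate 1 this difference was -17.5 (exact permutation p = 0.0286, the smallest that 3 against 4 arrays can give), and without replicate 4 it was -5.83. On day 16 the numbers were 36.8 ± 1.5 and 36.5 ± 17.1 (difference 0.250, exact permutation p = 1.00). The sign of this difference turned without cyclic day 16 replicate 1 (-6.25) or 2 (-2.25) and without pregnant day 16 replicate 1 or 3 (-0.167 each). On day 20 the numbers were 46.0 ± 13.2 and 38.5 ± 10.5 (difference 7.5, exact permutation p = 0.543), and the difference was 2.17 without pregnant day 20 replicate 3, 12.8 without replicate 4, and 4.67 and 4.33 without cyclic day 20 replicates 2 and 4. Over the 12 pairs of a pregnant and a cyclic array that shared slide and column, the labelling spike-in differed by -0.0162 log10 units (exact permutation p = 0.475) and the hybridization spike-in by 0.0671 (exact permutation p = 0.403).

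**Figure D1:**
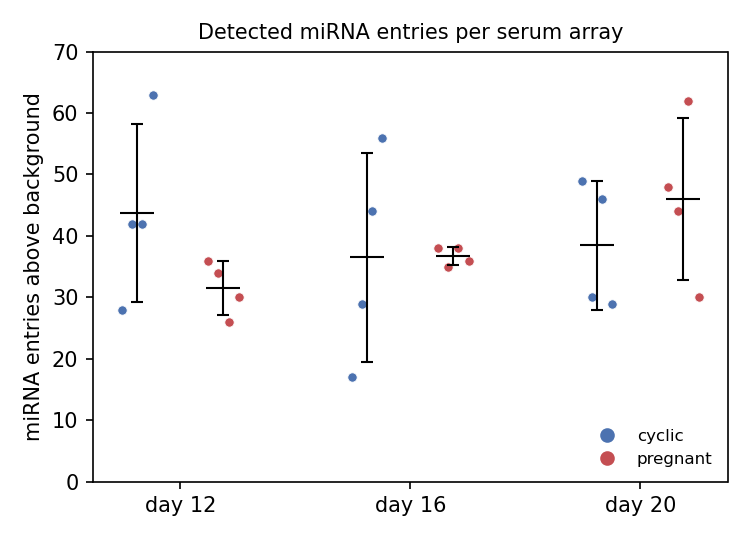
Number of miRNA entries above background per array (y axis) in the 6 groups (x axis, status and day). Points are arrays, and bars with error bars give the mean and SD of 4 arrays, which ran from 31.5 ± 4.44 (pregnant, day 12) to 46.0 ± 13.2 (pregnant, day 20).

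The brightest entries were ssc-miR-1285, with 23.7% of the signal of the 56 tested entries, and hsa-miR-720, with 19.9%. Both together took 43.7 ± 5.61% (SD, n = 24). Probes differ in how much signal a molecule gives, so these shares are not shares of molecules. In order of mean log2 signal, miR-1285 and miR-720 were followed by hsa-miR-1225-5p (8.02%), hsa-miR-1274b (7.55%), ssc-miR-4334 (4.99%), hsa-miR-138 (3.53%), ssc-miR-451 (3.96%), hsa-miR-630, hsa-miR-1202 and hsa-miR-638. The sequences of miR-720 and miR-1274b match transfer RNAs. MiR-451, the main miRNA of red blood cells, had the widest spread of the 56 entries between animals of a group (SD 1.40) and ran from -4.19 to 1.33 over the 24 arrays, a 45.7-fold range. This spread came mainly from cyclic animals of day 12 (SD 1.98) and day 16 (SD 2.6), against SDs of 0.28 to 0.75 in the other groups.

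Pregnant and cyclic animals were compared on day 12, when porcine conceptuses elongate and signal their presence to the mother. The lymphocyte miRNA miR-150 (hsa-miR-150) read -3.18 ± 0.50 in pregnant and -4.14 ± 0.58 in cyclic animals, where 3 of 4 arrays detected it. The difference was 0.96 (SE 0.50, interval -0.08 to 2.00, adjusted p = 0.571). The red-cell miRNA miR-16 (ssc-miR-16) went the other way, at -4.53 ± 0.11 in pregnant animals (2 of 4 arrays detected it) and -3.55 ± 1.03 in cyclic animals (3 of 4), a difference of -0.98 (SE 0.60, adjusted p = 0.571). The bright hsa-miR-939 differed by -0.46 (SE 0.19, interval -0.86 to -0.06, adjusted p = 0.571), with -0.54, -0.23 and -0.54 within the 3 slides. MiR-4334 differed by -0.29 (SE 0.16), and by -0.12 without pregnant day 12 replicate 2. MiR-92a (ssc-miR-92a), which is found in red cells, was detected on 2 cyclic and no pregnant arrays, and takes no fold. A further 5 entries leaned on a single animal. MiR-557 was detected on 1 cyclic array and no pregnant array (at least 1.14-fold lower in pregnant animals), miR-134 of the imprinted DLK1-DIO3 cluster likewise (at least 1.06-fold lower), and miR-4332 likewise with no bound. MiR-498 was detected on 2 cyclic arrays and no pregnant array (at least 1.02-fold lower), and miR-642b on 3 cyclic and 1 pregnant arrays (difference -0.90, SE 0.56). Cyclic arrays that did not detect miR-557, miR-134 or miR-498 entered these bounds at the floor, so the true folds may be smaller. Without cyclic day 12 replicate 4 the differences of miR-557, miR-134 and miR-4332 were 0.00, that of miR-498 0.01 and that of miR-642b 0.05. Normexp background correction turned the sign of miR-92a, miR-134, miR-4332 and miR-498, and quantile normalization that of miR-498. None of these passed: limma called 0 of 56 entries on day 12, with 1 at an unadjusted p under 0.05 and 2.80 expected by chance. With the level of miR-451 as a covariate, chosen after the data were seen, miR-16 passed (-1.04, adjusted p = 0.0298, range over its alternatives 0.0298 to 1.00). The number of arrays limits the precision. For the 39 entries above background on at least 1 array of both groups the median interval was ± 0.69 (1.62-fold), and 22 of these had an interval inside a 2-fold change either way. Entries above background on no array of a group lie at or near the floor in that group and exclude nothing. Entries detected on few arrays of a group mostly lie at the floor on the others, which narrows their interval. MiR-197, for example, had an SE of 0.15 with 1 array detected in each group. The 22 are therefore not all exclusions of a 2-fold change.

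On day 16, when the conceptus attaches to the uterine lining, miR-223, miR-486 and miR-451 read higher in pregnant animals without passing the test. MiR-223 (hsa-miR-223), a miRNA of myeloid cells and platelets, was -1.56 ± 0.96 in pregnant and -2.96 ± 1.57 in cyclic animals (3 of 4 arrays detected it). The difference was 1.40 (SE 0.62, interval 0.10 to 2.69, 2.6-fold, adjusted p = 0.711). It was 3.13, 1.51 and -0.57 within the 3 slides, so slide 3 went the other way, and it ran from 0.73 to 1.82 over the settings leaving out 1 array. MiR-486 (ssc-miR-486), a red-cell miRNA, was -2.56 ± 0.30 and -3.55 ± 1.04, a difference of 1.00 (SE 0.49, adjusted p = 0.711), and 0.53 at the lowest on leaving out 1 array. MiR-451 differed by 1.12, with the sign turned on slide 3 (-1.43), and ran from 0.16 to 1.90 on leaving out 1 array. The lowest value of all 3 came without cyclic day 16 replicate 1. Not all entries from blood cells went this way: miR-93 of the red-cell list was lower (-0.04), as were 2 of 4 platelet entries. MiR-150 differed by 0.24, and its sign turned without cyclic day 16 replicate 1 or 2 (-0.17 each), without pregnant day 16 replicate 3 (-0.11) and with normexp background correction (-0.29). Lower in pregnant animals were hsa-miR-638 (difference -0.77, SE 0.39, adjusted p = 0.711) and a group of dim entries detected on 2 cyclic and no pregnant arrays. These were the muscle miRNA miR-133a-3p (at least 1.15-fold lower), miR-212 (at least 1.09-fold lower, and of the opposite sign in the value table of the series) and miR-766 (at least 1.27-fold lower). Each bound leaned on 1 cyclic array: it was 1.03-fold without replicate 4 for miR-133a-3p and 1.02-fold without replicate 3 for miR-212 and without replicate 2 for miR-766. The cyclic arrays that did not detect these entries entered the bounds at the floor, so the true folds may be smaller. MiR-138 (0.38, SE 0.26) and bta-miR-188 (0.48, SE 0.36) were above background on every array and did not pass, and without cyclic day 16 replicate 1 they were 0.06 and 0.10. The human entry hsa-miR-188-5p went slightly the other way (-2.87 in pregnant and -2.81 in cyclic animals). MiR-125b was detected on 3 pregnant and no cyclic arrays and takes no fold, and miR-30b-5p differed by 0.22. Both were 0.00 without pregnant day 16 replicate 3 and turned sign with normexp background correction. Limma called 0 of 56 entries on day 16, with 2 at an unadjusted p under 0.05, and the median interval of the 42 entries measured in both groups was ± 0.67. Without the arrays with the fewest and the most detected entries, a setting chosen after the data were seen, miR-638 (-1.15) and miR-133a-3p passed (adjusted p = 0.0455 each, range over their alternatives 0.0455 to 1.00).

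On day 20, during early placentation, miR-150 stood out. It was -2.56 ± 0.25 in pregnant and -4.22 ± 0.30 in cyclic animals, with every pregnant array (-2.91 to -2.32) above every cyclic array (-4.44 to -3.78). The difference was 1.66 (SE 0.50, interval 0.62 to 2.70, 3.17-fold higher in pregnant animals, adjusted p = 0.183), which did not pass over 56 entries. Within the slides the difference was 1.32, 2.05 and 1.64, and with slide as a block the adjusted p was 0.260. Compared on the 8 day 20 arrays alone it passed (adjusted p = 0.00308), as it did with a replicate block (adjusted p = 0.0417) and with miR-451 as a covariate (1.19, adjusted p = 0.0396), while over all alternatives the difference ran from 0.11 to 2.05 and the adjusted p from 0.00308 to 1.00. The lowest value came from normexp background correction, under which the median of all entries lay at -0.65. Another 2 probes of the entry are on the array, of which the 1 above background gave 1.23.

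On day 20, 41 of 56 entries read higher in pregnant animals and 14 lower, which depended on the scaling: 30 were higher with quantile normalization, 28 with the median in place of the 75th percentile, 27 with the total gene signal, 23 with an added offset and 9 with normexp background correction, against 49 without normalization. MiR-16 differed by 1.13 (SE 0.60, adjusted p = 0.552), with 0.89, 0.84 and 1.39 within the slides and 0.73 without pregnant day 20 replicate 3, and miR-25 (bta-miR-25) by 0.90 (SE 0.52). MiR-451 differed by 1.08, miR-223 by 0.97 (0.61 without cyclic day 20 replicate 1) and miR-486 by 0.78 (1.18 without pregnant day 20 replicate 2). With normexp background correction the sign turned for miR-16 (-0.09), miR-25 (-0.23), miR-486 (-0.13) and miR-92a (-0.72 in place of 0.26, which was 0.16 without pregnant day 20 replicate 1 and 0.17 without replicate 3). MiR-423-5p was detected on 3 pregnant arrays and 1 cyclic array and differed by 0.54 (SE 0.20, adjusted p = 0.346). Without pregnant day 20 replicate 2 it was 0.73 (adjusted p = 0.0433), the only passing entry of that setting, whereas over the 8 settings leaving out 1 array the adjusted p reached 0.853. MiR-370 of the DLK1-DIO3 cluster differed by 1.21 (SE 0.63, and 0.77 without pregnant day 20 replicate 4), miR-23a by 0.75 (SE 0.38), miR-1280 by 0.55 (SE 0.28), miR-623 by 0.58 (SE 0.30) and miR-138 by 0.45 (SE 0.26), all at an adjusted p of 0.552. For miR-23a and miR-1280 the other probe gave the opposite sign (-0.01 and -0.25), and normexp background correction turned both and also miR-370, miR-623 and miR-423-5p. The scanner software's total gene signal turned miR-1280 as well (-0.004). Limma called 0 of 56 entries on day 20, with 2 at an unadjusted p under 0.05. The median difference over all entries was 0.17.

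**Figure D2:**
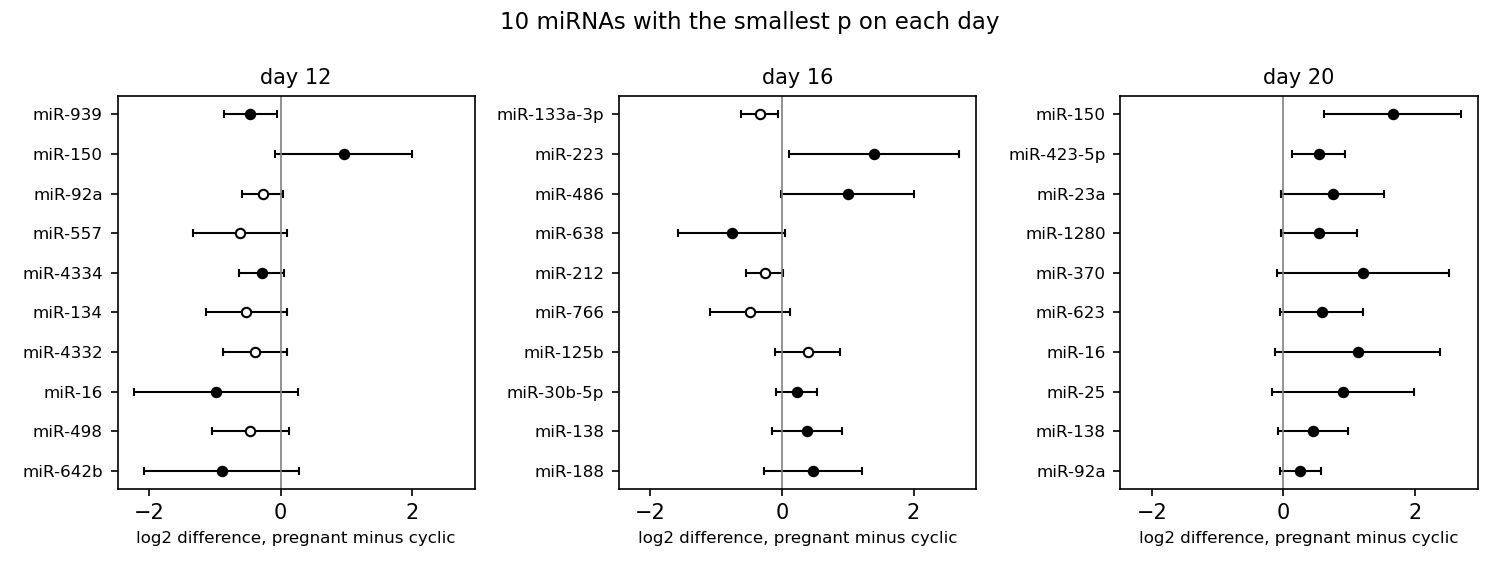
Pregnant minus cyclic difference (log2) of the miRNAs named for days 12, 16 and 20, with 95% confidence intervals from limma. Open circles mark entries not above background on any array of a group; on day 20 miR-150 has the largest difference (1.66, interval 0.62 to 2.70).

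Over the mean of the 3 days, 12 pregnant against 12 cyclic animals, miR-150 was again first, at 0.96 higher in pregnant animals (SE 0.29, interval 0.35 to 1.56, 1.94-fold, adjusted p = 0.192). It passed with quantile normalization (1.03, adjusted p = 0.0354), with a replicate block (adjusted p = 0.0436), without cyclic day 16 replicate 3 (1.10, adjusted p = 0.0309) and without cyclic day 16 replicate 4 (1.08, adjusted p = 0.0493), and over its alternatives the adjusted p ran from 0.0309 to 1.00 and the difference from 0.18 (normexp background correction) to 1.28 (the value table of the series). The bright miR-138 followed (0.40, SE 0.15, adjusted p = 0.385), then miR-486 (0.67, SE 0.28), miR-1280 (0.37, SE 0.16, with -0.04 from its other probe), miR-223 (0.74, SE 0.36) and miR-370 (0.67, SE 0.36). MiR-623 (0.33), miR-720 (0.27), miR-423-5p and miR-125b completed the 10. The last 2 were above background on no array of at least 1 group, so no size is given. Of these, miR-623, miR-423-5p and miR-125b changed sign with normexp background correction. Limma called 0 of 56 entries, with 4 at an unadjusted p under 0.05, all higher in pregnant animals. For the 36 entries measured in all 6 groups the median interval was ± 0.44 (1.36-fold), and 26 had an interval inside a 2-fold change either way. Values at the floor narrow the intervals of entries detected on few arrays, so the 26 are not all exclusions of such a change.

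Whether the status effect itself differed between days was tested directly. The largest shift was that of miR-16, whose pregnant minus cyclic value was 2.11 higher on day 20 than on day 12 (SE 0.85, interval 0.34 to 3.88, adjusted p = 0.607) and 1.75 higher on day 16 than on day 12 (SE 0.85, adjusted p = 0.597). With normexp background correction these shifts all but vanished (0.05 and 0.13). MiR-223 shifted by 1.55 from day 12 to day 16 (SE 0.88), by 0.88 without cyclic day 16 replicate 1 and by 0.46 with normexp background correction. Also among the first 3 by p were miR-133a-3p from day 12 to day 16, and miR-92a and miR-423-5p from day 12 to day 20. All 3 were above background on no pregnant array of day 12, so no size is given. The sign of miR-133a-3p turned in the value table of the series, and that of the other 2 with normexp background correction. From day 16 to day 20 the status effect of miR-150 was 1.422 higher (SE 0.71, interval -0.05 to 2.89, adjusted p = 0.998) and that of miR-4331 0.62 higher (0.40 without cyclic day 16 replicate 4). MiR-212, also among the first 3, was above background on no pregnant array of day 16 and takes no size. MiR-4331 and miR-212 turned sign with normexp background correction, and miR-4331 also in the value table. Limma called 0 of 56 entries in each of the 3 tests, with 0, 3 and 1 at an unadjusted p under 0.05. The value table of the series gave 1 passing entry for day 20 against day 12, miR-30b-5p (adjusted p = 0.0262, range over that test's alternatives 0.0262 to 0.832). This entry was above background on no array of 3 of the 4 groups in that test, so the pass has no measured level behind it.

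Between days within pregnant animals, miR-223, miR-16 and miR-23a read higher after day 12, whereas miR-150 was -3.47 on day 16 against -3.18 on day 12. MiR-223 was -3.37 ± 0.26 on day 12, -1.56 ± 0.96 on day 16 and -1.50 ± 0.31 on day 20, which is 1.81 (SE 0.62, 3.50-fold, adjusted p = 0.256) and 1.87 (SE 0.62, 3.65-fold, adjusted p = 0.144) above day 12. MiR-16 was 1.69 above day 12 on day 16 (SE 0.60, adjusted p = 0.256). MiR-23a, of the miR-23a/27a/24 cluster, was detected on 1 of 4 arrays on day 12 and on all 4 on the later days, when it lay 1.02 (SE 0.38) and 1.22 (SE 0.38) higher, against 0.09 and 0.14 with normexp background correction, and the former was 0.66 without pregnant day 16 replicate 3. MiR-423-5p was detected on no pregnant array on day 12 and on 3 on day 20 (at least 1.11-fold higher, 1.01-fold without pregnant day 20 replicate 3, with the sign turned by normexp background correction). Without pregnant day 20 replicate 2 it passed (adjusted p = 0.0257), and over the alternatives the smallest adjusted p of this test ran from 0.0257 to 0.598. Limma called 0 of 56 entries for day 16 against 12, 20 against 12 and 20 against 16, with 4, 7 and 0 at an unadjusted p under 0.05. The leading entries from day 16 to day 20 were miR-150 (0.91), miR-92a (0.25) and miR-638 (0.61), each at an adjusted p of 1.00.

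In cyclic animals the leading differences between days were mostly in dim entries. MiR-133a-3p was detected on no array on day 12, on 2 on day 16 (at least 1.27-fold higher, 1.13-fold without cyclic day 16 replicate 4) and on 1 on day 20. MiR-212 was detected on 1, 2 and 0 arrays (at least 1.02-fold lower on day 20 than on day 16, with no bound without cyclic day 16 replicate 3). For day 20 against day 16 normexp background correction turned the sign of both. MiR-92a was 0.27 lower on day 16 than on day 12 (0.17 without cyclic day 12 replicate 3), with the opposite sign under normexp background correction. MiR-1274b lay 0.53 higher on day 20 than on day 12 (SE 0.28, adjusted p = 0.856), and 0.23 higher without cyclic day 12 replicate 4. MiR-4334 lay 0.26 lower on day 20 than on either day, and 0.17 lower than on day 12 without cyclic day 12 replicate 1 and 0.15 lower than on day 16 without cyclic day 16 replicate 1. MiR-557 lay 0.60 lower on day 20 than on day 12, and without cyclic day 12 replicate 4 this was 0.02 in the other direction, as it was with normexp background correction (0.56). Limma called 0 of 56 entries for day 16 against 12, 20 against 12 and 20 against 16, with 1, 0 and 1 at an unadjusted p under 0.05.

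Of the 19 lists, 4 had enough tested members for a set test. The red-cell list (miR-451, miR-486, miR-16, miR-25, miR-92a and miR-93) had 5 of 6 members higher in pregnant animals on day 16 (mean 0.60) and 6 of 6 on day 20 (mean 0.72). With normexp background correction 2 of 6 were higher on day 16 (mean 0.04) and 1 of 6 on day 20 (mean -0.18), so the direction on day 20 turned. The same offset added to the processed signal alone left means of 0.09 and 0.34. The other scalings kept means of 0.47 to 1.56 on day 16 and 0.41 to 1.02 on day 20. On day 16 camera called the list higher (adjusted p = 0.0413), but the call was lost with an estimated correlation (adjusted p = 0.706, correlation 0.611), and over its alternatives the adjusted p ran from 0.0200 to 0.706. Fry gave an adjusted p of 0.828. On day 20 the list had an adjusted p of 0.0788 by camera and 0.181 by fry. On day 12 its mean was -0.19 (2 members higher, 3 lower, adjusted p = 0.549 by camera), which normexp background correction turned to 0.07 and the offset alone to 0.05. On that day 4 of 6 members were measured in both groups. Over the mean of the days the mean was 0.38 (adjusted p = 0.315 by camera), against 0.16 with the offset alone and -0.03 with normexp background correction. No member of any list passed, and 0 passed adjusted over the list alone.

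**Figure D3:**
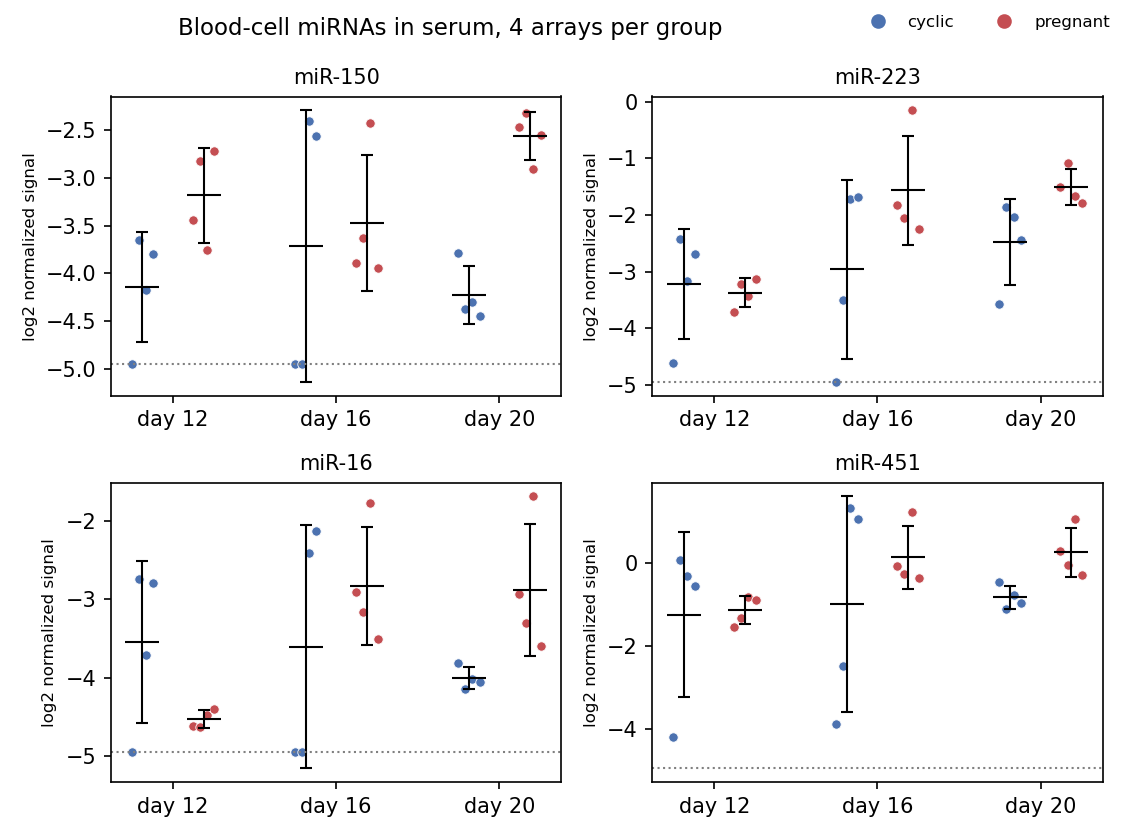
Level (log2 of the signal relative to the array's 75th percentile, y axis) of miR-150, miR-223, miR-16 and miR-451 in the 6 groups (x axis). Points are arrays, black bars with error bars the mean and SD of 4 arrays, and the dotted line the floor at -4.95; on day 20 all pregnant values of miR-150 lie above all cyclic values.

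The platelet list (miR-223, miR-197, miR-22-3p and miR-24) had means of -0.01, 0.31 and 0.34 on days 12, 16 and 20 and 0.21 over the days. Members not above background in a group enter at the floor: 2 of 4 were measured in both groups on day 12 and 3 on day 16, so the day 12 mean and its sign say little. The median was 0.00 on day 12, where fry pointed up, and -0.00 on day 16. The smallest adjusted p was 0.260, by fry on day 20. The list of the miR-17 cluster and its paralogs (miR-25, miR-92a and miR-93) had means of -0.17 (1 of 3 measured in both groups), 0.24 and 0.45 and 0.17 over the days, with 3 of 3 members higher on day 20 (adjusted p = 0.181 by fry and 0.238 by camera). The angiogenesis list (miR-23a, miR-27a and miR-296) had means of -0.10, 0.09 and 0.20 and 0.06 over the days, with miR-23a alone measured in both groups on days 12 and 16. Its median on day 20 was -0.07, opposite to its mean, and over the days the median (-0.02) and fry pointed down. The smallest adjusted p of this list was 0.553, by camera on day 20. Normexp background correction turned the sign of the mean of all 3 lists on every day. An offset added to the processed signal alone did so for all 3 on days 12 and 16, and for the angiogenesis list on day 20 (-0.06). The platelet mean on day 12 was also positive with quantile normalization (0.02) and a floor 4 times lower (0.06), and the angiogenesis mean on day 16 negative without normalization (-0.07).

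The remaining lists had too few tested members. White cells had miR-150 and miR-223, inflammation miR-223 and miR-125b, and the DLK1-DIO3 cluster miR-134 and miR-370 of 56 entries on the array. A single tested member each was left of muscle (miR-133a-3p), the miR-30 family (miR-30b-5p), the miR-99 and miR-125 clusters (miR-125b), the ovary (miR-212) and the primate C19MC cluster (miR-498, of 24 entries). The pig has no such cluster. None of the 6 liver, 7 miR-200, 9 let-7, 10 X-linked miR-424 and miR-503, 8 miR-371 and miR-302, 4 miR-183 and 10 smooth muscle and stroma entries was above background on any array.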

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

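The count of entries expected at the brightness of an array and the share with another probe above background, given below, were both chosen before the result was seen. In 142 groups of 4 arrays, over 40 entries, 12 had a single array whose gap to the nearest other array took more of the group's range than Dixon's 95% critical value, against 7.10 expected by chance. That expectation assumes normal values without a floor. For miR-642b, miR-423-5p, miR-623, miR-125b and miR-498 the other arrays lay at or near the floor, which pushes the gap towards the whole range. The 12 are therefore no evidence of more outliers than chance gives.

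MiR-451, the red-cell miRNA, was far lower in cyclic day 12 replicate 1 (-4.19) than in the other cyclic animals of that day (-0.56 to 0.08, gap 0.851 of the range). Cyclic day 16 replicate 1, the array with the fewest detected entries (17), was high for miR-939 (-1.24 against -1.88 to -1.82, gap 0.906) and low for miR-638 (-1.99 against -0.59 to -0.37, gap 0.867). In cyclic day 12 replicate 4 miR-642b was high (-1.11 against -4.95 to -4.78, gap 0.956). In replicate 3 of the same group miR-423-5p (-4.65 against -4.95 to -4.94, gap 0.993) and miR-623 (-4.46 against -4.95 to -4.91, gap 0.916) were high. In pregnant day 12 replicate 2 the brightest entry, miR-1285, was high (2.43 against 1.48 to 1.61, gap 0.865). In pregnant day 16 replicate 3 miR-125b was high (-3.39 against the floor of -4.95, gap 1) and miR-630 low (-1.94 against -0.63 to -0.36, gap 0.832), and in replicate 1 of that group miR-720 was low (1.15 against 2.16 to 2.31, gap 0.869). In pregnant day 20 replicate 4 miR-498 was marginally above the floor where the others lay on it (-4.93 against -4.95, gap 1), and miR-23a was low (-4.12 against -3.54 to -3.48, gap 0.915). No difference between days in the status effect passed its test.

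Outside the tested entries, 27 entries were above background on only 1 to 3 arrays, and 20 of these were so on cyclic day 12 replicate 4, 16 of them nowhere else. The brightest of the 20 on that array were miR-1181 (-2.0), miR-877 (-2.17), miR-874 (-2.23) and miR-520b (-2.45). The next highest number, 7, was on pregnant day 20 replicate 3. Isolated bright spots are argued against, since 17 of the 20 (85.0%) had another probe above background on the same array. The probes of an entry are meant for the same miRNA, so the share with another probe does not cover unspecific binding. MiR-520b belongs to the primate C19MC cluster, which the pig lacks, so its probe did not read a pig miRNA of that name on this array. Unspecific binding therefore stays open for the rare entries. This array also had the highest 75th percentile (1381, next 966). The other 23 arrays, all dimmer, predict 55.9 entries at that brightness (95% prediction interval 40.3 to 71.6) against 63 found. A brighter array may thus account for the total, but this test does not cover how many of the entries were rare. Only 43 of the 63 were tested entries, against 55 of 62 on pregnant day 20 replicate 3. Brightness as the cause of the rare entries therefore stays open. What made it brighter stays open, and no biological explanation was tested.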

How the results depend on the processing

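Settings without the arrays with the fewest and the most detected entries, with miR-451 as a covariate, and with an offset of 50 added to the processed signal, were chosen after seeing the data. Of the values of named miRNAs under settings other than leaving out an array, 896 kept direction and side of the threshold, 49 reversed, 3 fell to exactly 0 and 8 passed; leaving out an array, 809 kept both, 6 reversed, 5 fell to exactly 0 and 4 passed. Of the counts and list tests, 220 kept theirs under the former settings, 8 moved, 5 reversed, 1 fell to exactly 0 and 1 was lost; under the latter 159 kept theirs, 4 moved, 4 reversed and 1 passed. Signal over background limits what can be measured: 35.3% of tested values lay at the floor, below which no difference shows, and without a filter over 0.5 of the residual variances were exactly 0, so that setting is unreliable. The value table, centred within each day, could not give day contrasts within a status. It followed scanner differences with correlations of 0.894, 0.881 and 0.83 and slopes of 0.833, 0.996 and 0.838 on days 12, 16 and 20. Its array medians were 0.00313, 0.0189, -6.65e-05 and -0.000479 (cyclic day 12), 0.00205, -0.000152, -6.65e-05 and 6.65e-05 (pregnant day 12), 0.0835, 0.0226, -0.00225 and -0.00119 (cyclic day 16), 0.0162, -0.00229, -0.000418 and 0.000418 (pregnant day 16), -0.00122, 0.0394, -0.000538 and 0.000538 (cyclic day 20), and 0.00835, -0.00133, -0.00159 and 0.00127 (pregnant day 20). The median pregnant minus cyclic difference on days 12, 16 and 20 was 0.00, -0.03 and 0.17, against 0.01, -0.02 and 0.00 with quantile normalization, 0.00, 0.08 and 0.00 with the median in place of the 75th percentile, -0.12, -0.01 and -0.01 with the total gene signal, 0.00, -0.01 and 0.11 with the mean over probes, -0.08, 0.04 and 0.27 with the lower floor, -0.46, -0.07 and 0.26 with the 75th percentile over all probes, -0.34, 0.00 and 0.44 without normalization, 0.16, -0.25 and -0.65 with normexp, 0.15, -0.22 and -0.06 with the added offset and -0.10, 0.33 and 0.21 in the value table. The 10 brightest names were the same 10 under quantile normalization, normexp, the mean over probes and the lower floor. Same-numbered arrays of a day shared a slide and a column, but their deviations correlated at -0.750 to 0.498 (median 0.0616), and 5 of 12 cyclic samples matched their own number best, so the model has no block for the number and the block is given as an alternative.

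Normexp reversed most. It changed spot signal, background and offset together. The offset alone, added to the processed signal, reversed 9 of the 21 pregnant against cyclic values that normexp reversed: on day 12 miR-92a (0.16), miR-4332 (0.055) and miR-498 (0.081), on day 16 miR-125b (-0.033), miR-30b-5p (-0.070), miR-25 (-0.004) and miR-150 (-0.25), and on day 20 miR-423-5p (-0.002) and miR-92a (-0.092). The cause of the other 12 was not tested. Values of entries not above background in a group rest on the floor and are not sizes. On day 12 normexp gave 0.17 for miR-92a, 0.035 for miR-134, 0.13 for miR-4332 and 0.12 for miR-498. On day 16 it gave -0.10 for miR-125b, -0.14 for miR-30b-5p, -0.054 for miR-25, -0.009 for miR-16 and -0.29 for miR-150. On day 20 it gave -0.65 for miR-423-5p, -0.46 for miR-23a, -0.064 for miR-1280 and for miR-370, -0.50 for miR-623, -0.086 for miR-16, -0.23 for miR-25, -0.72 for miR-92a and -0.13 for miR-486. Over the mean of the days it gave -0.11 for miR-623, -0.21 for miR-423-5p and -0.22 for miR-125b. For the status effect it gave -0.89 for miR-92a and -0.85 for miR-423-5p (day 20 against 12), and -0.48 for miR-212 and -0.31 for miR-4331 (day 20 against 16). Within cyclic animals it gave 0.19 for miR-92a (day 16 against 12), 0.56 for miR-557 (20 against 12), and 0.42 for miR-133a-3p and 0.53 for miR-212 (20 against 16), and within pregnant animals -0.11 for miR-423-5p (20 against 12).

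For the following, and for the counts that changed on leaving out arrays, the cause was not tested. Several sizes shrank to about 0.5 of their value or less with their sign kept. With normexp these were miR-939 (-0.24), miR-16 (-0.14), miR-642b (-0.29) on day 12, miR-223 (0.50), miR-486 (0.22), miR-188 (0.12) and miR-451 (0.48) on day 16, miR-150 (0.11) and miR-223 (0.34) on day 20, and miR-486 (0.12), miR-1280 (0.08), miR-223 (0.30) and miR-370 (0.08) over the mean of the days. Within pregnant animals they were miR-16 (0.55, day 16 against 12), and miR-150 (0.49) and miR-92a (0.02) for day 20 against 16. The 75th percentile over all probes gave 0.10 for miR-150 on day 12 and 0.15 for miR-138 over the days, quantile normalization 0.12 for miR-138 on day 16 and 0.01 for miR-720 over the days, the total gene signal 0.004 for miR-138 on day 20, no normalization -0.38 for miR-638 on day 16, and the value table of the series gave 0.29 for miR-150 in the status effect of day 20 against 16. Without cyclic day 16 replicate 1 miR-25 was 0.27 and miR-16 0.33 on day 16. Quantile normalization reversed miR-498 on day 12 (0.079), and gave 1 passing entry over the mean of the days, miR-150. It turned the direction of the platelet list by camera on day 12 (adjusted p = 0.897), the angiogenesis list by camera on day 20 (0.683) and over the days by camera (0.830) and by fry (0.541). The floor 4 times lower reversed miR-92a on day 12 (0.033), and the total gene signal miR-1280 on day 20 (-0.004). The value table reversed miR-212 on day 16 (0.65), miR-133a-3p in the status effect of day 16 against 12 (0.23) and miR-4331 in that of day 20 against 16 (-0.24), and passed 1 entry for day 20 against 12, miR-30b-5p. A replicate block passed 1 entry on day 20 and 1 over the mean of the days, and the day 20 groups compared alone passed 1, each time miR-150. With an estimated correlation the camera call of the red-cell list on day 16 was lost (adjusted p = 0.706). The day 16 difference in detected entries was 0 by the gene-level flag and -1.25 when all used spots had to be above background. With miR-451 as a covariate 1 entry passed on day 12 (miR-16) and 1 on day 20 (miR-150), and miR-150 reversed on day 16 (-0.25).

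Without the arrays with the fewest and the most detected entries 2 entries passed on day 16 (miR-638 and miR-133a-3p), and miR-150 reversed on day 16 (-0.17). On day 12 the values were 0 for miR-557, 0 for miR-134, 0 for miR-4332, 0.006 for miR-498 and 0.049 for miR-642b. Replicate 4, the array left out on day 12, was the only cyclic array with miR-557, miR-134 and miR-4332 above background. Leaving out 1 array in turn gave ranges of -0.82 to 0 for miR-557, -0.70 to 0 for miR-134, -0.52 to 0 for miR-4332, -0.61 to 0.006 for miR-498 and -1.23 to 0.049 for miR-642b on day 12, with the top values without cyclic day 12 replicate 4. On day 16 the ranges were 0 to 0.52 for miR-125b and 0 to 0.30 for miR-30b-5p (0 without pregnant day 16 replicate 3), and -0.17 to 0.68 for miR-150. MiR-557 in cyclic animals, day 20 against 12, ran from -0.81 to 0.018. The count of passing entries ran from 0 to 1 on day 20, over the mean of the days and in pregnant animals for day 20 against 12. It was 1 on day 20 and in pregnant animals without pregnant day 20 replicate 2 (miR-423-5p, 0.41 to 0.73 and 0.45 to 0.77 over these settings), and 1 over the mean without cyclic day 16 replicate 3 or 4 (miR-150, 0.82 to 1.10). The difference in detected entries ran from -17.5 to -5.83 on day 12 and from -6.25 to 6.75 on day 16.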

Other observations

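The tests of array brightness and labelling below were chosen before their results were seen, whereas the tests of red-cell against white-cell entries, of miR-451 as a covariate, of the array row, of the tRNA-derived entries and of the splits that part same-numbered arrays were chosen after.

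Entries whose sequences match transfer RNAs were bright, though signals of different probes are not comparable as amounts. MiR-720, miR-1274a, miR-1274b and miR-1280 together took 29.3 ± 7.30% (SD, n = 24) of the summed signal of the 56 tested entries. The share was 33.5 ± 6.35% in pregnant and 26.3 ± 11.3% in cyclic animals on day 12 (SD, n = 4), 26.8 ± 5.40% and 28.1 ± 9.32% on day 16, and 28.3 ± 4.88% and 32.9 ± 5.96% on day 20. Over the mean of the days pregnant minus cyclic was 0.421 percentage points (interval -6.07 to 6.91, permutation p = 0.897), which leaves differences of up to several points open. The share of the same sum held by miR-451, miR-486, miR-16, miR-25, miR-150 and miR-223, all from blood cells, was 7.09% on average and ran from 1.78% to 16.0% over the 24 arrays. The first principal component of the tested entries took 47.8% of the variance, and its highest loadings were those of miR-451 (0.447), miR-223 (0.329) and miR-16 (0.310).

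The blood-cell miRNAs varied together between animals of a group, with a mean pairwise correlation of 0.760 for the 4 red-cell and 2 white-cell entries, against a median of 0.209 for random sets of the 35 entries detected on at least 12 arrays. On cyclic day 16 replicates 1 and 2 and cyclic day 12 replicate 1, miR-25, miR-16 and miR-150 lay at the floor together. The correlation without these arrays was not computed. With brightness regressed out the mean correlation was still 0.656, above the 95th percentile of random sets (0.408). This argues against a linear effect of array brightness as the whole cause. A linear fit cannot remove a floor shared by dim arrays, so brightness acting through the floor stays open. Uneven labelling stays open: the labelling spike-in and the mean of these entries had r = 0.133 (interval -0.342 to 0.554, permutation p = 0.601) and rho = 0.296 (permutation p = 0.234), r = 0.097 without the 2 farthest arrays and 0.822, 0.292 and 0.552 within the slides. Red-cell entries correlated with white-cell entries at 0.713 on average (random sets: median 0.223, 95th percentile 0.528), but these pairs are part of the pattern itself, so RNA released from blood cells in differing amounts stays open. Of the 6, miR-223 is also on the platelet and inflammation lists, the serum was centrifuged before storage, which removes cells but not released RNA, and no biological explanation was tested.

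Among 3 relations computed across the 24 arrays as deviations from group means, the array's 75th percentile went with the number of detected entries (r = 0.822, permutation p = 0.0003, adjusted 0.0009). Spearman's rho was 0.780 (permutation p = 0.00085), r was 0.740 without the 2 farthest arrays, and 0.953, 0.866 and 0.769 within the slides. With the mean of the blood-cell entries the 75th percentile had r = 0.690 (permutation p = 0.0490, adjusted 0.0735) and rho = 0.481 (permutation p = 0.0934), 0.50 without the 2 farthest arrays, and 0.774, 0.728 and 0.643 within the slides.

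MiR-150 was 1.66 higher in pregnant animals on day 20 (SE 0.50). Red-cell RNA as tracked by miR-451 is argued against as the whole cause, since with miR-451 as a covariate the difference was 1.19 (SE 0.30, interval 0.57 to 1.81). MiR-451 is a single marker measured with error and need not follow white cells. RNA released from blood cells as a whole, white cells included, therefore stays open for miR-150. Array brightness as the whole cause is argued against too, since with brightness as a covariate the difference was 1.29 (SE 0.39, interval 0.48 to 2.11, adjusted p = 0.198). The row of the array cannot be told apart from status. All 3 days share the rows, and the difference was 0.96 on day 12 and 0.24 on day 16. Between days 20 and 16 the effect differed by 1.422, with an interval of -0.05 to 2.89 that includes 0, so a row effect stays open. A difference tied to pregnancy itself stays open as an untested hypothesis, and the adjusted p over the 56 entries was 0.183.

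Other splits of the same samples were compared by the number of entries at an unadjusted p under 0.05, since limma called 0 entries in every contrast. Chance could not be excluded for pregnant against cyclic animals on day 12 (1 entry, 31 of 35 splits with as many, highest other 6), day 16 (2 entries, 20 of 35, highest other 20), day 20 (2 entries, 15 of 35, highest other 6) or their mean (4 entries, 17 of 100, highest other 11). The same held for the status effect of day 16 against 12 (0 entries, 100 of 100, highest other 13), 20 against 12 (3 entries, 23 of 100, highest other 11) and 20 against 16 (1 entry, 71 of 100, highest other 21). It also held in cyclic animals for day 16 against 12 (1 entry, 31 of 35, highest other 27), 20 against 12 (0 entries, 35 of 35, highest other 13) and 20 against 16 (1 entry, 25 of 35, highest other 21), and in pregnant animals for 20 against 16 (0 entries, 35 of 35, highest other 7). In pregnant animals only the real split of day 16 against 12 gave 4 entries (1 of 35, highest other 2), and only that of day 20 against 12 gave 7 (1 of 35, highest other 5). Taken singly, each had a share of 0.0286, the smallest that 35 splits can give, but these 2 were the extremes of 13 contrasts. Over the 13 contrasts the adjusted value was 0.186, and 2 contrasts at that smallest share could not have come under 0.05. Chance is therefore not excluded for these 2, and the splits cannot decide it.

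Several splits gave many more entries than the real ones. The highest count is the extreme of many splits, and how high it would run by chance was not computed. Whether it marks a structure of the samples therefore stays open, as does any cause. Parting the 4 brighter from the 4 dimmer arrays gave 27 entries in cyclic animals of days 12 and 16, the highest of all splits there, 7 on day 16 and 4 on day 20 against the real 2, and 1 on day 12. It was the highest in no other contrast: the highest others were 6, 20 and 6 for status on days 12, 16 and 20, and brightness gave 5 in cyclic animals of days 12 and 20 (highest 13), 12 of days 16 and 20 (highest 21), and in pregnant animals 1 of days 12 and 16 (real 4), 4 of days 12 and 20 (real 7) and 1 of days 16 and 20 (highest 7). Same-numbered arrays of a day shared slide and column, and of the 8 splits that part them, the real one among these, 7, 4 and 2 gave as many entries as the real one on days 12, 16 and 20 (highest other 4, 10 and 3). Parting by slide, the slide with 4 arrays of a day against the rest, gave 0 on each day.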
